A study of Homo sapiens with 6 samples.

How the data were processed

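The data were bulk RNA sequencing of A549 cells transfected with empty pcDNA3.1 or with a ZBTB16 plasmid, 3 libraries each, from total RNA prepared with Trizol and a TruSeq RNA kit, per the labels. The labels' extraction text names retinas while all other fields name A549 cells; the cells are treated here as A549. Each library's group and number come from the sample titles. Per the submitters' processing notes the tools include HISAT2 2.0.5 and the build hg38. The read counter, the strand setting, the filters and the normalization are not given in the sources used here.

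The deposited values are FPKM, read numbers scaled to gene length and library size, for 58735 genes, with each gene's length, position and biotype, per the file headers. All 58735 identifiers, names, positions and strands equal those of GENCODE 29, and the deposited gene length equals the summed length of the merged exons in that annotation for 100% of genes. FPKM times length was a whole multiple of a single step per library for 100% of values within 0.01, so the reads per gene could be recovered. The library size behind the authors' FPKM differed from the sum of recovered reads by -0.23% to 0.97%. The libraries held 15478010 to 17319971 such reads and between 23774 and 24206 genes with at least 1 read. Intervals and floors from reads cover counting error only. Libraries of a group differed by more than counting noise, with a mean chi-square per gene of 2.35 to 5.72 within groups, so none was treated as a repeat deposit of another.

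Genes with a mean FPKM of at least 1 over the 6 libraries, 12499 genes, were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using a trended robust prior and no covariate. Fold changes are on that scale, which understates changes of genes with low values. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. A count model was not the main test because the values are FPKM. Percent differences and ± values (SD) are of FPKM itself. For single genes an exact two-sided permutation test was added, which with 3 libraries against 3 cannot go below 0.1.

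Before the data were examined, 32 gene lists were fixed from textbook pathways, from described ZBTB16 targets and from markers of other cell types. The 27 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 27. Every list was run again with an estimated correlation, which 7 of the 12 passing lists kept, and with limma's fry, which asks whether a list's own genes move in a single direction. For each list the number of members that pass when adjusted over the list alone is also given. The list score of a library is the mean over members of log2(FPKM + 1) minus the empty-vector mean.

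The genes named were set by a rule fixed with the lists. ZBTB16 and WDHD1 come first, then up to 12 protein-coding genes in each direction with the largest change among those called whose groups did not overlap. From each list come up to 4 called members or, with none called, the member with the smallest p. With fewer than 10 genes called, the 10 protein-coding genes with the smallest p outside the calls are named as not passing. Lists of other cell types are represented by their gene of highest FPKM. Further members are named as examples of their lists and were chosen after their values were seen. Some genes that the rule names are not reported here.

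The alternatives were a pseudocount of 0.1 or 0.5, no filter, a mean FPKM of at least 5, protein-coding genes alone, median-ratio, quantile or equal-sum scaling, a constant prior, array weights, limma voom on the recovered reads, a fold-change minimum, the repeat number as a block, and leaving out each library. Camera with trended variance was added after the data were seen. The steps were tested on simulated reads drawn from the libraries' own means. Of 12513 genes, 50 were changed at each fold size, of which 49 at 1.25-fold, 1.5-fold and 2-fold and 48 at 4-fold passed the filter and were evaluated. Of those evaluated, the limma step on log2 FPKM recovered 12.2% at 1.25-fold, 67.3% at 1.5-fold, 81.6% at 2-fold and 100% at 4-fold, with 13 false calls. With no change simulated it made 0 calls. The list step recovered 2 of 2 lists shifted by 10% and called 0 others. Simulated genes varied independently of each other, so this does not measure false list calls where the genes of a list are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.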

Results

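RNA sequencing was carried out on A549 cells, an established human lung adenocarcinoma line, after transfection with the empty expression vector pcDNA3.1 or with a plasmid carrying ZBTB16. ZBTB16, also called PLZF, is a zinc finger transcription factor of the BTB domain family and is known mainly as a repressor. Each group had 3 libraries, numbered 1 to 3 in the labels. The values were FPKM per gene, and the reads recovered from them came to 16744238, 16528472 and 16515975 for the empty vector and to 15478010, 17033725 and 17319971 for ZBTB16. Mitochondrial transcripts took 6.02% to 6.54% of the reads and the 10 most abundant genes 7.22% to 7.54%. The labels do not say whether the repeats were separate cultures. The limma p-values of single genes therefore measure the spread between these libraries, which may be technical. Camera p-values at the preset correlation set a list against the other tested genes and do not measure that spread. They can be too small where the genes of a list are correlated. For the licensing list the camera adjusted p was 4.02e-18 at the preset and 0.0171 with an estimated correlation. The series title places ZBTB16 upstream of WDHD1, DNA replication and the cell cycle, so the comparison of ZBTB16 with empty vector asks which transcripts differ when the factor is supplied.

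ZBTB16 itself was the largest difference. Its gene (ENSG00000109906, hg38 chromosome 11, 114059593 to 114250676, plus strand) had 0 reads in each of the 3 empty-vector libraries. In the ZBTB16 libraries it stood at 426, 488 and 456 FPKM, a mean of 456 ± 31.0 (SD, n = 3), from 41881 to 53108 reads. These reads were 0.271% to 0.312% of each library. A count of 0 in the empty-vector group allows up to 3 reads over its libraries, or 0.00940 FPKM. Reads pooled over the 3 ZBTB16 libraries gave 457 FPKM, so the pooled level was at least 48661-fold higher with the plasmid, for counting error only. The log2 fold change on the log2(FPKM + 1) scale was 8.84 with a limma adjusted p of 4.36e-12. The exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. Reads from the plasmid and from the chromosomal gene were not told apart.

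WDHD1, a chromatin-bound factor that links the replicative helicase to DNA polymerase alpha, was at 5.60 ± 0.0691 FPKM with empty vector and at 4.65 ± 0.0873 FPKM with ZBTB16 (SD, n = 3 each). Its gene (ENSG00000198554) lies on the minus strand of chromosome 14 at 54938950 to 55027105. All 3 ZBTB16 values lay below all 3 empty-vector values, a difference of -17.0%. The log2 fold change of -0.22 (SE 0.051, 95% interval -0.34 to -0.11) did not pass over all genes, with a limma adjusted p of 0.167. Adjusted over the list of replication licensing and firing genes alone it was 0.00636 in limma. The exact two-sided permutation p was 0.1, the smallest possible. The series title names WDHD1, which may have been picked on these same libraries, so neither its own value nor the list's is independent evidence. Among the other 30 tested members of that list, 7 had a lower fold change than WDHD1.

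**Figure D1:**
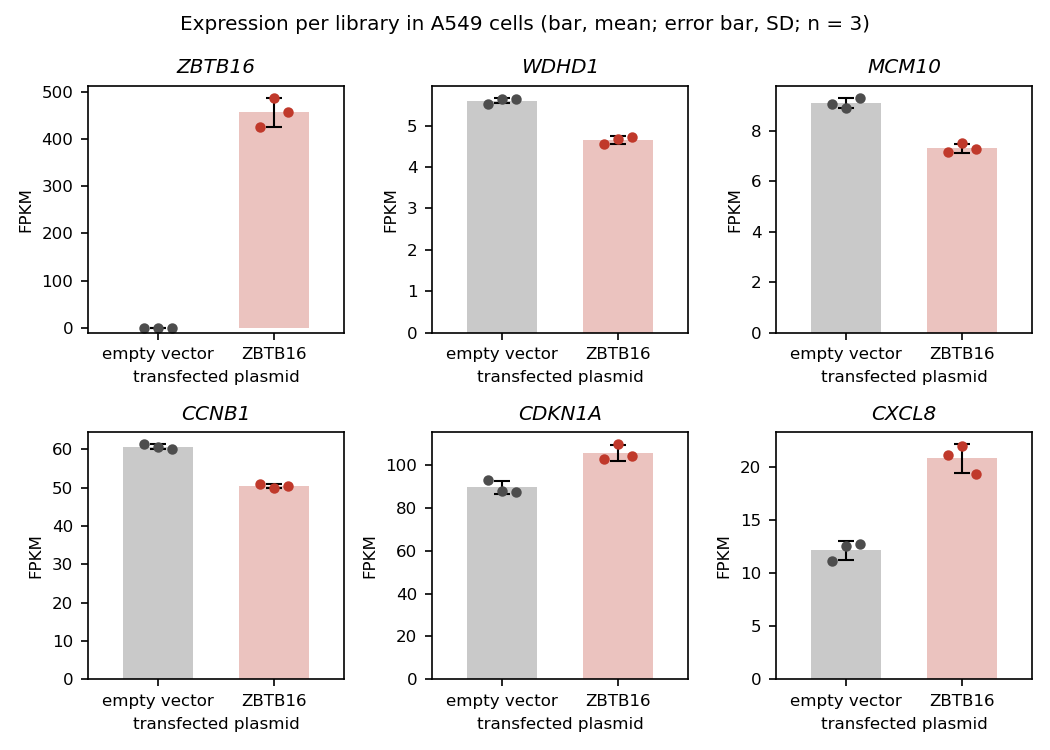
FPKM (vertical axes) of 6 genes in each library by transfected plasmid; bars give the mean, error bars the SD and points the 3 libraries. ZBTB16 was at 0 with empty vector and at a mean of 456 FPKM with its plasmid, while WDHD1 was at 5.60 and 4.65 FPKM.

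Lists of DNA replication, cell division and repair transcripts were lower with ZBTB16 as sets, by a small amount, with 147 of 155 tested members negative. In limma on log2 FPKM 0 of the 155 tested genes of 6 such lists passed over all 12499 genes, and 94 were lower at an unadjusted p under 0.05, whereas the 6 lists passed as sets in camera, of which the repair list lost its call with an estimated correlation (adjusted p = 0.0533). Over all genes 33 of the 155 were called with limma voom on the recovered reads and 15 in limma among protein-coding genes, all lower. The 33 were 8 licensing, 1 fork, 4 nucleotide, 4 G1/S, 14 G2/M and 2 repair genes. At a mean FPKM of at least 5, 13 of 116 were called, all lower, among them MCM10, TK1, CCNA2 and CCNB1 at limma adjusted p of 0.0328, 0.0243, 0.0280 and 0.0243. In the list of 31 tested origin licensing and firing genes, every member had a negative fold change, with a median log2 of -0.19 (camera adjusted p = 4.02e-18). Adjusted over the list alone, 20 of the 31 were lower and 0 higher. MCM10, which helps activate the replicative helicase, was at 9.11 ± 0.202 FPKM with empty vector and 7.32 ± 0.177 with ZBTB16, a log2 fold change of -0.28 with an adjusted p of 0.095. MCM4, MCM5 and MCM7, subunits of that helicase, had log2 fold changes of -0.24, -0.26 and -0.21. The licensing factor CDT1 was at -0.29 and its inhibitor GMNN at -0.26. Of the 25 tested fork synthesis genes 24 were negative, with a median of -0.15 (camera adjusted p = 7.15e-10), and 6 were lower adjusted over the list alone. The histone chaperone subunit CHAF1A had the smallest p there, with 11.8 and 10.1 FPKM and an adjusted p of 0.180. The sliding clamp PCNA was at 236 ± 6.10 and 207 ± 9.24 FPKM, adjusted p = 0.194.

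Nucleotide synthesis genes fell as a list as well, with 21 of 22 negative, a median of -0.12 and 10 lower adjusted over the list alone (camera adjusted p = 9.32e-09). Thymidine kinase TK1 was at 109 ± 7.43 FPKM with empty vector and 86.3 ± 2.50 with ZBTB16, a log2 fold change of -0.33 with an adjusted p of 0.095. Thymidylate synthase TYMS had a log2 fold change of -0.27. In the list of G1/S cyclins and E2F factors 17 of 20 were negative, with a median of -0.12 and 7 lower adjusted over the list alone (camera adjusted p = 4.44e-06). CCNA2, the S and G2 phase cyclin, was at 21.7 ± 0.314 and 17.5 ± 1.02 FPKM, with an adjusted p of 0.0982. E2F1 stood at 31.2 and 26.6 FPKM and E2F2 at 4.23 and 3.23, while cyclin D1 (CCND1) stood at 81.3 and 84.2.

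In camera at the preset correlation the smallest p was that of G2/M and mitosis, in which 31 of 32 genes were negative, the median was -0.25 and 28 were lower adjusted over the list alone (camera adjusted p = 3.79e-24). Its exception was the phosphatase CDC25B at 136 and 137 FPKM. CCNB1, the mitotic cyclin, was at 60.6 ± 0.651 FPKM with empty vector and 50.4 ± 0.546 with ZBTB16, a log2 fold change of -0.26 with an adjusted p of 0.0834. TOP2A was at 63.8 and 52.1 FPKM, PLK1 at 27.1 and 21.9, FOXM1 at 18.2 and 14.6, and the centromeric histone CENPA at 14.7 and 10.8. Homologous recombination and Fanconi repair genes were negative in 23 of 25, with a median of -0.14 and 7 lower adjusted over the list alone (camera adjusted p = 6.65e-09). With an estimated correlation between genes this list had an adjusted p of 0.0533 and its call was lost. The helicase BLM had the smallest p among them, at 3.77 and 2.81 FPKM with an adjusted p of 0.116. The other 5 lists of this theme kept their calls, at adjusted p from 0.0171 to 0.0331 with an estimated correlation. The themes of these lists follow the series title, so their direction is not independent evidence.

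**Figure D2:**
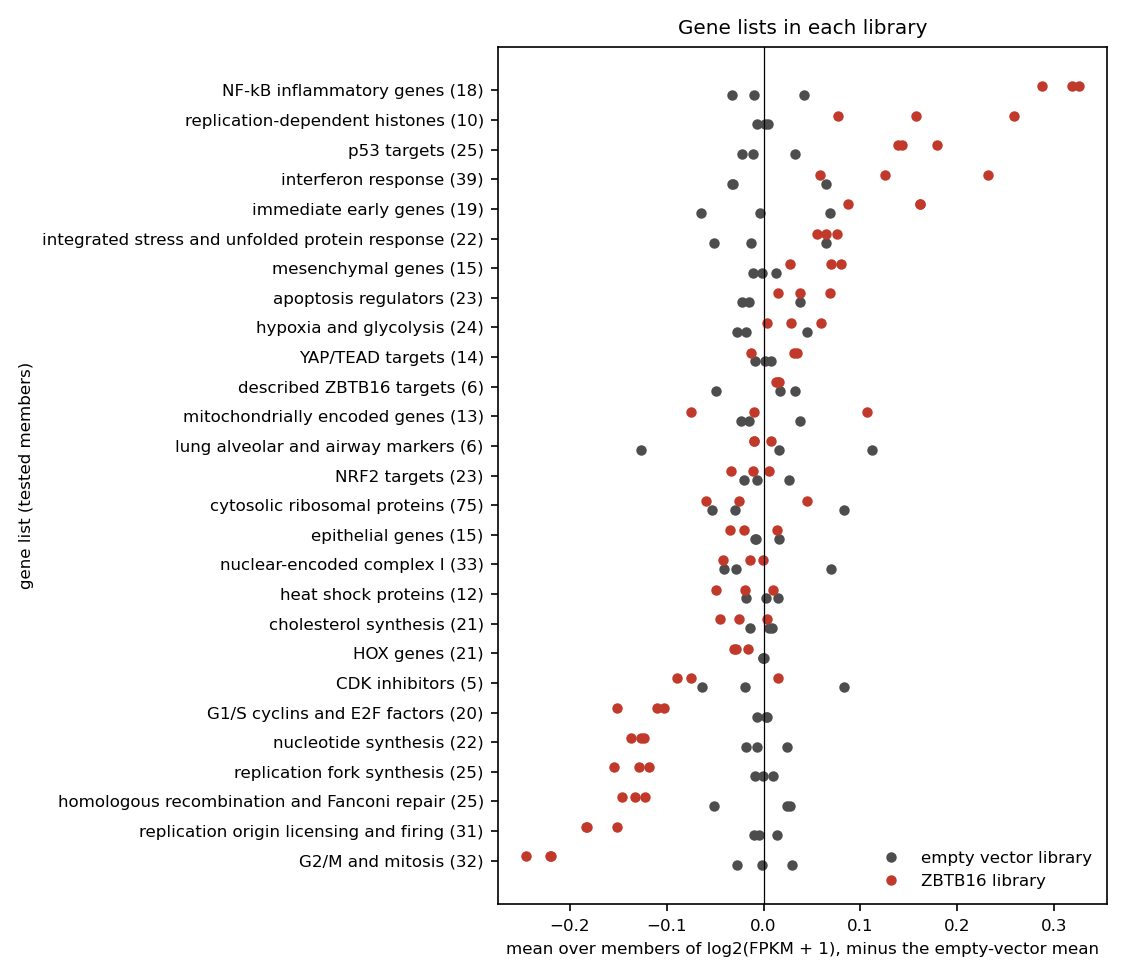
Mean over the tested members of each gene list of log2(FPKM + 1), minus the empty-vector mean (horizontal axis), for each of the 6 libraries and 27 lists (vertical axis, tested members in brackets). For G2/M and mitosis the 3 ZBTB16 libraries lie between -0.25 and -0.22, and for the NF-kB list between 0.29 and 0.33.

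Inflammatory transcripts controlled by NF-kB were higher with ZBTB16 as a list. All 18 tested members of that list had a positive fold change, with a median log2 of 0.29 (camera adjusted p = 3.36e-18, and adjusted p = 0.0171 with an estimated correlation). Over all genes 3 members passed, and 14 were higher adjusted over the list alone; with voom 9 passed over all genes and among protein-coding genes 7. The neutrophil chemokine CXCL8 (chromosome 4, 73740506 to 73743716) rose from 12.1 ± 0.887 to 20.8 ± 1.34 FPKM, a log2 fold change of 0.73 (SE 0.067, limma adjusted p = 0.0159). CXCL1 (chromosome 4, 73869393 to 73871242) rose from 48.2 ± 2.83 to 70.5 ± 2.99 FPKM, a log2 fold change of 0.54 with an adjusted p of 0.0234 in limma. TNFAIP3, an inhibitor of NF-kB signalling (chromosome 6, 137867188 to 137883312), rose from 10.7 ± 0.230 to 15.2 ± 0.913 FPKM, a log2 fold change of 0.46 with an adjusted p of 0.0389. For CXCL8 and CXCL1 the exact permutation p was 0.1, the smallest possible. With a library left out CXCL8 passed without empty-vector replicate 2 or ZBTB16 replicate 3 (0.0289 and 0.0290) and otherwise had limma adjusted p from 0.0503 to 0.0583, while CXCL1 and TNFAIP3 passed in none of the 6 such fits (0.0503 to 0.153). CXCL2 at 13.1 and 17.9 FPKM and CXCL5 at 100.2 and 129 did not pass, with adjusted p of 0.0669 and 0.0834, nor did IL6 at 0.994 and 1.69 FPKM (0.116). CXCL1 has close paralogs in CXCL2 and CXCL3, between which reads can be shared. Summed FPKM of the immune, fibroblast and endothelial markers was 7.07 ± 0.308 with empty vector and 7.14 ± 0.341 with ZBTB16.

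Genes outside that list also passed over all genes. SOD2, the mitochondrial superoxide dismutase (chromosome 6, 159669057 to 159745186), rose from 16.1 ± 0.372 to 22.8 ± 1.07 FPKM, a log2 fold change of 0.48 (adjusted p = 0.0234). Part of its exons is also annotated under a further identifier of the same symbol. The secreted glycoprotein STC2 rose from 19.0 ± 0.742 to 25.8 ± 1.09 FPKM (log2 0.42, adjusted p = 0.0389). IGFBP1, which binds insulin-like growth factors, rose from 53.1 ± 2.20 to 68.9 ± 1.96 FPKM (log2 0.37, adjusted p = 0.0454). The gene that fell was CPLX2, a complexin known from synaptic exocytosis (chromosome 5, 175796310 to 175884020), from 131 ± 6.80 to 97.0 ± 4.01 FPKM, a log2 fold change of -0.43 with an adjusted p of 0.0389. In each of these the 3 values of a group lay apart from the 3 of the other, which the naming rule required. The call of CPLX2 ended with no filter (limma adjusted p = 0.362), with a constant prior (0.185) and with any library left out (0.0795 to 0.144). Those of SOD2, STC2 and IGFBP1 ended in the same settings, at limma adjusted p from 0.0503 to 0.216 with a library left out.

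**Figure D3:**
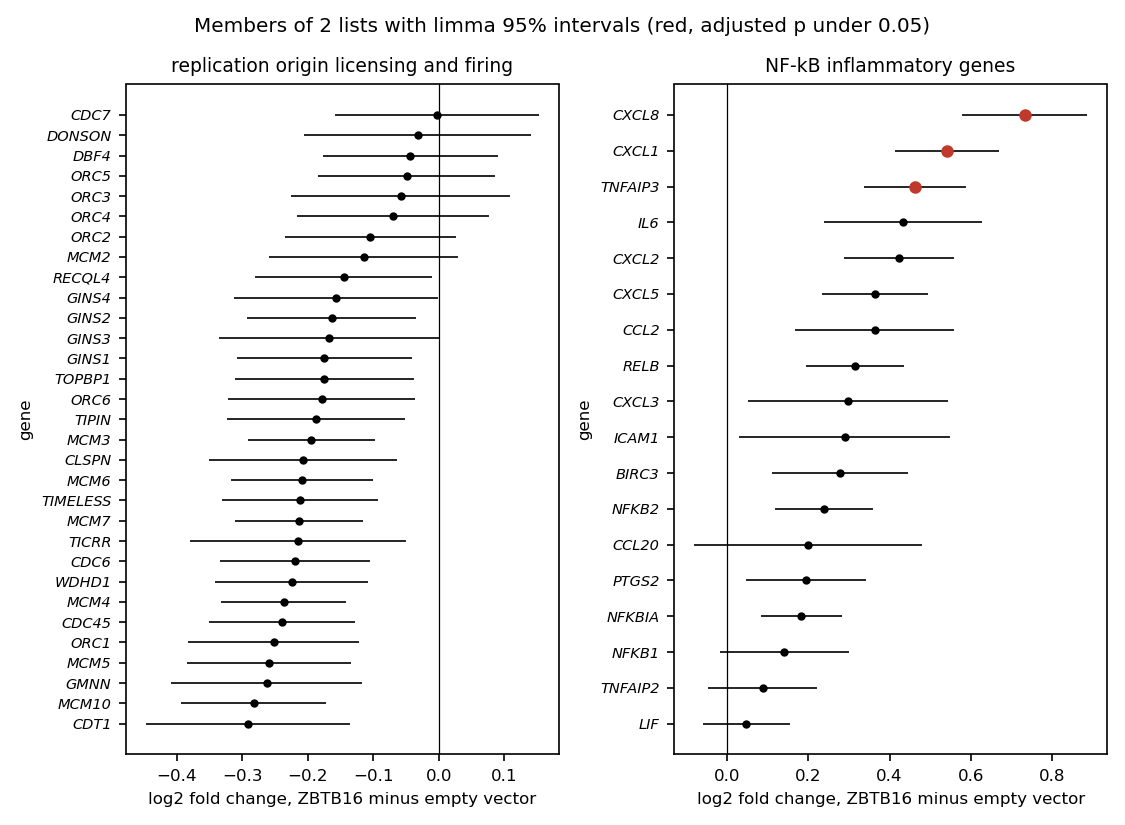
Log2 fold change, ZBTB16 minus empty vector (horizontal axes), of each tested gene (vertical axes) in the licensing and firing list and the NF-kB list; points are estimates on log2(FPKM + 1), bars limma 95% intervals, and red marks an adjusted p under 0.05 over all genes. All 31 licensing genes lie below 0 and all 18 NF-kB genes above it, and the 3 red genes are CXCL8, CXCL1 and TNFAIP3.

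In total 8 genes were higher with ZBTB16, the transfected gene among them, and 1 was lower, of 12499 tested with limma at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 635 higher and 646 lower genes, 10.2% of those tested. The groups did not overlap in 1015 genes that were higher and 1012 that were lower, 16.2% where chance gives 10%. Besides ZBTB16, no called gene reached an absolute log2 fold change of 1. The next 10 protein-coding genes by p did not pass, at adjusted p from 0.0669 to 0.0834. They were IRAK2, CXCL2, STC1, TRAF1, CCNB1, DDIT3, GLIPR1, CXCL5, ATF3 and C1QTNF1, and all but CCNB1 had positive fold changes. With voom all 10 passed, at limma adjusted p from 3.96e-05 to 0.00571. Exons of MARS on the opposite strand cover 27.2% of DDIT3 and those of KRR1 cover 24.2% of GLIPR1, and whether counting used the strand is not given in the sources used here. The counts of calls moved with the filter and the model: 56 higher and 33 lower among protein-coding genes, 44 and 31 at a mean FPKM of at least 5, 111 and 92 with limma voom on the recovered reads, and ZBTB16 alone with no filter or with a constant prior. Without empty-vector replicate 1, 2 or 3 the fit called 1, 4 and 1 genes higher, of which 1, 2 and 1 were among the 8, and 0, 1 and 0 lower. Without ZBTB16 replicate 1, 2 or 3 it called 2, 1 and 3 higher, of which 1, 1 and 2 were among the 8, and 0, 0 and 2 lower. The shared genes were ZBTB16 and, where there were 2, CXCL8, and no lower gene in these fits was CPLX2.

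Targets of p53 rose as a list, with 24 of 25 positive, a median log2 of 0.15 and 8 higher adjusted over the list alone (camera adjusted p = 2.64e-09, and adjusted p = 0.0195 with an estimated correlation). Over all genes 0 of them passed in limma on log2 FPKM, where 11 were higher at an unadjusted p under 0.05, while limma voom called 5 higher, CDKN1A, PHLDA3, PLK2, GADD45A and BTG2, and limma among protein-coding genes 4. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was at 89.6 ± 3.01 FPKM with empty vector and 106 ± 3.74 with ZBTB16, a log2 fold change of 0.23 with an adjusted p of 0.116. PLK2 was at 30.2 ± 0.312 and 37.5 ± 1.80 FPKM (adjusted p = 0.0834), and the damage-responsive GADD45A at 24.8 and 34.2. The 5 tested CDK inhibitors did not move together (camera adjusted p = 0.703). Adjusted over that list alone CDKN1A was higher and CDKN2C, at 10.7 and 8.70 FPKM, lower.

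Another 4 lists were higher by camera but lost their call with an estimated correlation. Of 39 tested interferon response genes 37 were positive, with a median log2 of 0.12 and 6 higher adjusted over the list alone (camera adjusted p = 1.02e-09, and adjusted p = 0.329 with an estimated correlation). IFNB1 was at 2.70 ± 0.584 and 4.38 ± 0.324 FPKM (adjusted p = 0.145). The mean score of this list in ZBTB16 replicate 1, 0.058, lay below that of empty-vector replicate 2, 0.064. Immediate early genes were positive in 16 of 19, with a median of 0.14, 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.26e-06, and adjusted p = 0.197 with an estimated correlation). The stress-induced factor ATF3 was at 7.74 ± 1.04 and 12.3 ± 1.12 FPKM (log2 0.61, adjusted p = 0.0834), and NR4A1, the member that was lower, at 7.91 and 6.41. Replication-dependent histone genes were positive in 8 of 10 tested, with a median of 0.23, 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00119, and adjusted p = 0.0657 with an estimated correlation). The 5 were HIST1H1C, HIST1H2BD, HIST1H4H, HIST1H2AC and HIST1H2BK, and the 1 was HIST1H2BJ. Several of these genes, HIST1H2BK and HIST1H1C among them, are known to yield polyadenylated transcripts as well. HIST1H1C was at 62.5 ± 2.45 and 76.2 ± 3.56 FPKM (adjusted p = 0.0992). With no filter on low values this list had an adjusted p of 0.0579. Mesenchymal genes were positive in 11 of 15, with a median of 0.066 and 2 higher adjusted over the list alone (camera adjusted p = 0.0347, and adjusted p = 0.197 with an estimated correlation). The integrin chain ITGA5 was at 22.5 and 26.7 FPKM (adjusted p = 0.175). The mesenchymal call ended without empty-vector replicate 2 or 3 or without ZBTB16 replicate 1 or 3, at adjusted p of 0.0574, 0.101, 0.171 and 0.107.

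The remaining lists did not pass, at camera adjusted p from 0.228 to 0.776 and list medians from -0.08 to 0.06. They were CDK inhibitors, apoptosis regulators, described ZBTB16 targets, HOX genes, YAP/TEAD targets, epithelial genes, lung alveolar and airway markers, integrated stress and unfolded protein response, heat shock proteins, NRF2 targets, cholesterol synthesis, hypoxia and glycolysis, nuclear-encoded complex I, mitochondrially encoded genes and cytosolic ribosomal proteins. Without empty-vector replicate 1 the apoptosis, stress, hypoxia and ribosomal protein lists passed as higher, at adjusted p of 0.0492, 0.0442, 0.0447 and 0.0170, while without ZBTB16 replicate 1 the ribosomal list passed as lower (0.0407). Of the 22 tested members of the stress list 10 had positive and 12 negative fold changes. Adjusted over the list alone 3 were higher, DDIT3, ATF3 and PPP1R15A, and 0 lower. Its median log2 was -0.01 and its mean 0.07. The mixed p of fry, which tests change in either direction, was 0.000173, not adjusted over the lists. That p was also low for described ZBTB16 targets (0.000383), CDK inhibitors (0.000777) and apoptosis regulators (0.00113), so it does not single out the stress list. For other lists it was high, as for cytosolic ribosomal proteins (0.806). Of the 6 tested genes described elsewhere as ZBTB16 targets, CCNA2 was lower and DUSP6, at 4.01 and 4.97 FPKM, higher adjusted over the list alone. MYC was at 53.1 and 54.6 FPKM. KRT19 (28.9 and 33.1 FPKM) was the epithelial gene higher adjusted over the list alone. Among the other lists, members with the smallest p in theirs were PMAIP1 (23.4 and 27.7 FPKM), HOXC13 (10.2 and 12.01), AXL (83.4 and 89.0), ABCA3 (9.57 and 10.3), HSPA8 (317 and 337), SRXN1 (18.7 and 15.7), PFKFB4 (3.97 and 5.18), NDUFS6 (41.4 and 37.5), MT-ATP8 (78.5 and 72.0) and RPL21 (85.3 and 91.3). None of these passed over its own list. MT-ATP6 overlaps 22.2% of MT-ATP8 and a further annotated gene, AL121758.1, 85.0% of SRXN1, and RPL21 has processed pseudogene copies, so their reads can be shared.

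Lists with fewer than 5 tested members had no set test. The 4 tested metallothioneins gave 0 calls, with MT2A at 275 ± 27.0 and 314 ± 22.6 FPKM. Markers of tissues other than the cell line were low. The labels' extraction text speaks of retinas, but the retina marker with the highest level, OPN1SW, was at 3.04 ± 0.313 FPKM with empty vector and 3.09 ± 0.952 with ZBTB16, and the retina markers summed to 5.25 and 4.89 FPKM. COL1A1 of fibroblasts was at 2.06 and 2.01 FPKM, CD14 of immune cells at 3.43 and 3.30, and PECAM1 of endothelium at 0.134 and 0.136. Each of the retina, fibroblast and immune lists had 1 member above the filter and the endothelial list 0, and none of the 3 tested markers passed (adjusted p from 0.899 to 0.995).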

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

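Camera with trended variance was chosen only after the data were seen; all other alternatives were set before. ZBTB16 stayed higher in every alternative in which it was tested, and WDHD1 stayed lower and short of the threshold in all of them, at limma adjusted p from 0.0567 (voom) to 0.453 (no filter). Counts of genes higher and lower, 8 and 1 as reported, were 1 and 0 with no filter, 1 and 0 with a constant prior, 1 and 0 at an absolute log2 fold change of at least 1, 44 and 31 at a mean FPKM of at least 5, 56 and 33 among protein-coding genes, 13 and 3 with quantile normalization, 29 and 3 with array weights, and 111 and 92 with voom. The voom calls included all 9 reported genes. The settings with at least 5 FPKM or protein-coding genes test fewer genes, 7071 and 10808, and also fit the prior to those genes alone. The cause of the differing counts was not tested for any setting. Genes lower were 2 with a pseudocount of 0.1 and 2 with ZBTB16 left out and equal sums. Leaving out a library gave 1 to 4 genes higher and 0 to 2 lower, with fewer samples in each fit, and 5 to 10 lists higher and 6 to 7 lower, the 10 without empty-vector replicate 1. Lists higher, 6 as reported, were 2 with an estimated correlation (NF-kB and p53) and 3 with fry (NF-kB, p53 and replication-dependent histones). The histone list had a fry adjusted p of 0.0192 and the repair list, which was lower, 0.0122. The interferon, immediate early and mesenchymal lists did not pass with fry (adjusted p = 0.227, 0.106 and 0.0953). The 6 replication, cell cycle and repair lists, and the NF-kB, p53, interferon and immediate early lists, passed in all 18 camera settings with the preset correlation that moved a list's p. OPN1SW, which passed nowhere, turned to 0.0015 with quantile normalization and ranged from -0.13 to 0.20 with a library left out, positive without empty-vector replicate 2 (0.05) or ZBTB16 replicate 3 (0.20). Same-numbered libraries deviated from their group means with correlations of 0.07, 0.05 and -0.04. Libraries 1 and 2 of each group correlated best with their own number in the other group, and libraries 3 did not. With 3 libraries per group and such small correlations, these values neither show nor exclude a pairing by number. With the replicate block 12 genes were higher and 3 lower, CPLX2 no longer among them (limma adjusted p = 0.0515). For the named genes, 646 results under alternatives kept direction and side of the threshold, 73 passed newly, 63 no longer passed and 3 turned. At this depth and with 3 libraries per group, limma recovered 12.2% of the 49 evaluated genes with the smallest simulated change, and voom 36.7%. Their false calls in that simulation were 13 and 15. Neither depth nor replicate number was varied.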

Other observations

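Among families of transcription factors annotated in the deposited table, 15 had at least 10 tested genes. The bZIP family, which holds ATF3, JUN and DDIT3, was higher with ZBTB16 as a set (36 genes, median log2 of 0.06, camera adjusted p = 0.00124), and the E2F family was lower (10 genes, median -0.09, adjusted p = 0.00142). Both had an adjusted p of 0.132 with an estimated correlation, so neither call held there. Of the 39 tested interferon response genes, the 3 with the highest level with empty vector were IFI6, ISG15 and IFIT3. With empty vector IFI6 was at 649 ± 31.3 FPKM, ISG15 at 446 ± 24.2 and IFIT3 at 125 ± 6.12, against 681 ± 67.5, 469 ± 11.1 and 143 ± 10.6 with ZBTB16. No untransfected cells were analysed here, so these levels have no baseline.

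Of the tests that follow, those on WDHD1 as a list member and on the response to plasmid DNA were chosen only after the result was seen. The first pattern is the lower level of the 6 replication, cell cycle and repair lists, in which 147 of 155 genes were negative with a median log2 of -0.17. Genes matched on length, GC content and mean FPKM gave medians from -0.02 to 0.02 in 1000 sets, and the difference of -0.18 argues against a bias of length or GC. Under 3 scalings the median nearest to 0 was -0.17, which argues against library size or normalization. Of the 10 splits of the 6 libraries, 1 passed as many lists, the real one with 12, and the highest other passed 10. These counts cover every tested list in either direction, not the lower lists alone. With 3 libraries against 3 the splits are too few to exclude chance. With an estimated correlation the real split passed 7 and the others 0. That contrast cannot decide the question, since the other splits mix the groups and the group difference then enters the estimated correlation. WDHD1 lay within the spread of its list, with 23.3% of the other members lower. This shows only that WDHD1 was not an outlier in a list whose theme follows the series title. A candidate explanation, not tested further, is that its transcript moved with the 6 lists. These are not an S phase program alone, since G2/M and mitosis had the lowest median log2 (-0.25). Replication-dependent histones had a positive median (0.23), though their call was lost with an estimated correlation. Whether WDHD1 drives the change of the 6 lists cannot be read from these libraries. Since each plasmid is its own group, the lower level of these lists cannot be told apart from an unequal response to the plasmid preparations.

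The second pattern is the higher level of NF-kB genes. Against genes matched on length, GC and FPKM the list median differed by 0.30, which argues against such a bias. The summed FPKM of immune, fibroblast and endothelial markers differed by 0.0697 (SE 0.265) while the NF-kB list's sum rose by 118 FPKM (SE 7.82), which argues against reads from those cells. An unequal response to the 2 plasmid preparations stays open and cannot be told apart from an effect of ZBTB16, since each plasmid is its own group: the interferon list had a positive median but an adjusted p of 0.329 with an estimated correlation. The rise may therefore come from the factor or from the transfection. This limit holds for the higher p53 list too.

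For the number of changed genes, 1 of the 10 splits gave as many, the real one with 9, and the highest other gave 1; the splits are too few for a share under 0.05. A negative hypothesis was that other BTB zinc finger genes move with the transfected one. The 34 tested ZBTB genes other than ZBTB16 had a mean log2 fold change with a 95% interval of -0.02 to 0.04. Their camera adjusted p was 0.863. The interval treats the genes as independent and leaves out the spread between libraries. With an estimated correlation of 0.042 between them it is too narrow. Within that limit it argues against a shift of the family by 0.1 or more.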
